A study of Sus scrofa with 23 samples.

How the data were processed

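Lung tissue of 23 pigs was measured by RNA sequencing, 1 library per pig and none pooled. The deposited table held raw read counts per gene for every library, and beside them gene start, end and length, which count here as other annotation fields that the authors joined to the counts. The authors' notes name HISAT and DESeq2, while their versions and roles, the program that counted the reads and the genome build are not given in the sources used here. All values of the count columns were whole numbers, and all 30335 genes with an NCBI gene ID carried the start and end that the RefSeq annotation of Sscrofa11.1 gives them. The table had 31170 entries, of which 835 were unnamed additions without a symbol and 5482 were at 0 in every library. The series design states 12 infected and 12 uninfected pigs, and 11 infected libraries were analysed here. Groups were taken from the labels, which give 4 groups by infection and diet. The pigs were 10 weeks old and had been fed their diet for 28 days, per the labels, which give no sex, sampling time or sequencing batch. Replicate numbers name different pigs, so that no pairing was used in the main model.

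Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes with low counts were removed with filterByExpr by group, which left 17657 genes and set aside 13513. TMM factors were computed and a quasi-likelihood model with robust estimation and 1 mean per group was fitted to all 23 libraries. The common dispersion was 0.0853, a biological coefficient of variation of 0.292. The contrasts were infection under each diet, PAC in uninfected and in infected pigs, their interaction, and infection and PAC averaged over the other factor. All tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors were taken as the absolute log2 fold change over the square root of F. CPM were counts over the total of the tested genes in each library times its TMM factor, and log2 CPM used a prior count of 2. Library totals lay between 14751598 and 19009017 counts. For a gene at 0 the limit is 3 counts of the raw total, which covers counting error only, since reads without molecular identifiers are not independent molecules.

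Gene lists for cell types, pathways and responses of the lung, 51 in number with 694 members, were fixed before the data were examined, as were the contrasts, tests, naming rule and most alternatives. Of the members 645 were found by symbol or synonym and 609 passed the filter, and 49 lists with at least 3 members tested were run through camera of limma with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes. Fry called 4 lists for infection under the control diet, 6 under the PAC diet and 0 in the PAC and interaction contrasts. The naming rule took, per contrast, the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a symbol and a mean of at least 1 CPM, up to 4 members with the smallest adjusted p for each list described, and a fixed panel of genes of worm infection. Scores were means of log2 CPM over a list, or for the clock score the mean of ARNTL and NPAS2 minus that of NR1D1, NR1D2, PER3, TEF and DBP, and were compared by exact permutation tests over all regroupings. An airway cartilage list was written after the data were seen.

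The procedure was tested on simulated data with 50 genes changed at each of 4 sizes per comparison and independent libraries, without the structure among libraries found here. It recovered between 32% and 50% of 1.5-fold changes, between 82% and 92% of 2-fold changes, between 90% and 98% of 3-fold changes and between 88% and 94% of 4-fold changes, with 5 to 11 false calls per comparison and 0 lists called. The changed genes were drawn from those with an average log2 CPM above 1, so that these shares do not cover genes at lower levels. Genes were simulated independently of each other, so that the 0 lists are no check of the list test on correlated genes. Alternatives set at that time were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test, only the 2 groups compared, the replicate number as a replicate block, voom with sample quality weights, EIF1AY, the only Y-linked gene that passed the filter, as a covariate, 1 surrogate variable, an estimated correlation for the lists, and leaving out each library in turn. Alternatives added after seeing the data were replicate numbers 1 to 3 against 4 to 6, an airway cartilage score, a clock score, and a term for or removal of 7 libraries that stood apart. Also added then were the panel genes under the filter in a fit of 25688 genes without it, the eosinophil slope with libraries left out, and 2 further clock scores. These were ARNTL, CLOCK and NPAS2 minus the other 10 clock genes of the fixed list, and ARNTL and NPAS2 minus NR1D2, PER3 and TEF. For each count 100 regroupings of the libraries, the real one included, were drawn with a fixed seed. No pair of libraries was a duplicate: the lowest chi-square per gene between any pair was 12.2. Left out were GC content, since no genome sequence was used here, and reads, alignments and splice forms, which were not analysed here.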

Results

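RNA was sequenced from the lung of 23 pigs, with 1 library per pig. Some pigs had been given eggs of Ascaris suum, the large roundworm of the pig, whose larvae pass through the lung before they return to the gut. The diet was either a control diet or the same diet with 1% proanthocyanidins (PAC), polyphenols taken here from grape seed. There were 6 uninfected pigs on the control diet, 6 uninfected pigs on the PAC diet, 6 infected pigs on the control diet and 5 infected pigs on the PAC diet. Infected pigs received 5000 eggs and were killed 14 days later. Raw counts per library summed to between 14751598 and 19009017. The mean totals were 17394000 (SD 1553100, n = 6) in uninfected pigs on the control diet and 16443000 (SD 1372100, n = 6) on the PAC diet. In infected pigs they were 16889000 (SD 1280500, n = 6) on the control diet and 15929000 (SD 305940, n = 5) on the PAC diet. Gene levels are given as CPM, counts per library total of the tested genes after scaling by its TMM factor (mean ± SD). Changes are log2 fold changes from an edgeR model fitted to all 23 libraries, with adjusted p over the 17657 genes tested.

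Under the control diet, the lungs of infected pigs held higher levels of eosinophil-associated genes than those of uninfected pigs. CCR3, the eotaxin receptor of eosinophils, lay at 3.14 ± 1.13 CPM in uninfected pigs (n = 6) and at 13 ± 4.86 in infected pigs (n = 6), and ALOX15, a 15-lipoxygenase, at 2.53 and 14.8 CPM. CEBPE, a transcription factor of granulocyte differentiation, lay at 0.681 and 4.90 CPM. The circadian clock genes differed as well: ARNTL and NPAS2, of the activating arm of the clock, were higher in infected pigs, while PER2, PER3, NR1D1, NR1D2, DBP and TEF, of its repressing and output arms, were lower. ARNTL went from 7.09 ± 1.16 to 24.8 ± 3.34 CPM and PER3 from 64.8 ± 12.7 to 28.0 ± 2.71 CPM (n = 6 each).

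The question was which lung genes differed with infection when no PAC was fed. The edgeR test called 18 genes, 12 higher and 6 lower in infected pigs, while 1727 genes had an unadjusted p under 0.05 and 883 would by chance. DESeq2 called 67 and voom with sample weights 263. Among called genes with a symbol and a mean of at least 1 CPM the largest rises were those of OLIG2 (log2 fold change 4.70, SE 0.79, adjusted p = 0.00806), a transcription factor of the oligodendrocyte lineage, CEBPE (2.85, SE 0.51, adjusted p = 0.0142) and ALOX15 (2.56, SE 0.38, adjusted p = 0.00206). Next came OLIG1 (2.48, SE 0.42, adjusted p = 0.00908) and CCR3 (2.05, SE 0.34, adjusted p = 0.00777). OLIG2 spanned 0 to 0.258 CPM in uninfected and 0.64 to 4.63 CPM in infected pigs, so that its fold change rests on few reads in uninfected pigs. ARNTL rose by 1.81 (SE 0.15, adjusted p = 3.19e-07) and NPAS2 by 1.06 (SE 0.12, adjusted p = 2.56e-05), and UNC5CL, AP5S1 and NFIL3, a transcription factor linked to the clock, rose by 1.23, 0.81 and 0.80 (adjusted p = 0.0143, 0.0333 and 0.0466). DBP fell by 1.61 (SE 0.29, adjusted p = 0.0143), NR1D1 by 1.45, PER3 by 1.21 (SE 0.12, adjusted p = 3.79e-06), TEF by 1.16 (SE 0.14, adjusted p = 0.000143) and PER2 by 0.96 (SE 0.15, adjusted p = 0.00548). NR1D2 went from 101 to 43.5 CPM (adjusted p = 0.00206). For each of these 16 genes all 6 infected libraries lay beyond all 6 uninfected libraries, except for PER2, for which 5 of 6 did. The remaining called genes, LOC100622306 (1.38) and LOC100522787 (2.58), carry no symbol and fall outside the naming rule, and were chosen after their values were seen. On the pig reference genome Sscrofa11.1, CCR3 (gene ID 414373) spans 29251950 to 29286470 of chromosome 13, ALOX15 (396971) 52287174 to 52295873 of chromosome 12, ARNTL (100037286) 45895637 to 46025174 of chromosome 2 and PER3 (100627898) 68487634 to 68548718 of chromosome 6.

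Uninfected libraries numbered 1 to 3 and infected control diet library 1, 7 libraries in all, stood apart from the rest. Of the libraries compared here, 3 of the 6 uninfected and 1 of the 6 infected ones belonged to them. With a term for these 7 libraries CCR3 still rose (2.01, adjusted p = 0.0101), as did ALOX15 (2.44, adjusted p = 0.00254) and ARNTL (1.91, adjusted p = 2.43e-08), and the number of genes called went up to 232, among them all 18. Without the 7 libraries 193 genes were called, 10 of the 18 among them, and CCR3 (1.69, adjusted p = 0.0606), ALOX15 (2.14, adjusted p = 0.0536) and CEBPE (2.45, adjusted p = 0.0602) no longer passed. A score was taken over 500 genes that differed between uninfected libraries 1 to 3 and 4 to 6. In it uninfected control diet libraries 4 to 6 (-0.579 to -0.363) lay below all infected ones (lowest -0.274). No regroupings were run on these fits, so that the 232 and 193 genes need not all be due to infection. Among libraries numbered 1 to 3 CCR3 differed by 2.43 and among those numbered 4 to 6 by 1.70 (3 against 3 libraries each; adjusted p = 0.113 and 0.0969). Leaving out single libraries ended the call of CEBPE without uninfected control diet library 1, 2 or 3 (adjusted p = 0.064, 0.0549 and 0.055). DBP lost its call without uninfected library 4 or infected library 1 or 5 (0.0511, 0.0541 and 0.0587), and UNC5CL without uninfected library 1, 2 or 3 or infected library 5 (0.0742, 0.0782, 0.0562 and 0.0595). AP5S1 lost its call in 8 and NFIL3 in 9 of the 12 left-out libraries, and the other 11 named genes kept theirs in all 12.

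**Figure D1:**
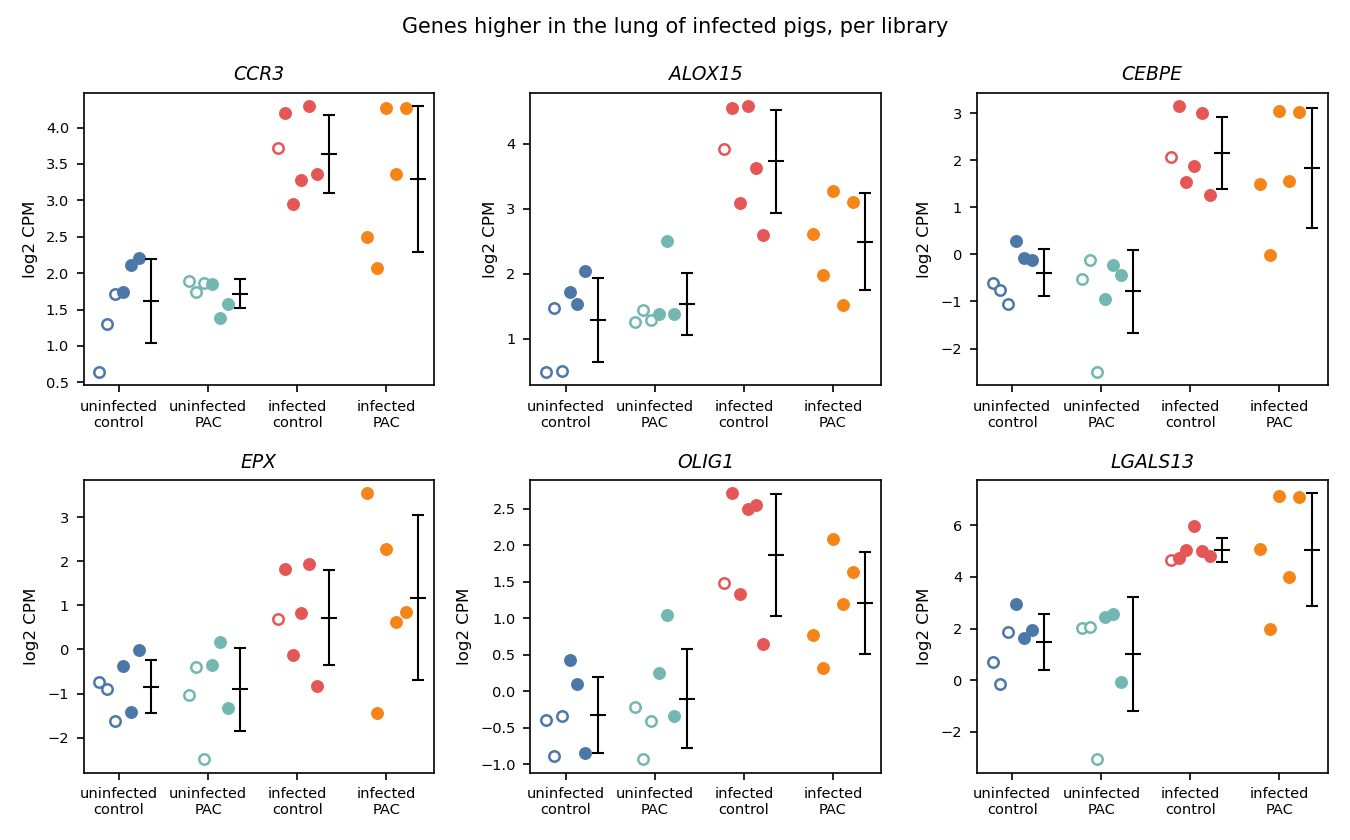
Log2 CPM (vertical axes) of CCR3, ALOX15, CEBPE, EPX, OLIG1 and LGALS13 in each of the 23 libraries, by group, with bars for the mean ± SD and open symbols for the 7 libraries that stand apart. Under the control diet all 6 infected libraries lie above all 6 uninfected ones for CCR3, ALOX15, CEBPE, OLIG1 and LGALS13, and 4 of 6 do for EPX.

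Gene lists fixed before the data were examined were tested as sets in the same contrast, and camera with its preset correlation called 13 of 49, 6 toward higher and 7 toward lower values in infected pigs. The eosinophil markers rose: 6 of 7 members lay above 0 with a median of 1.5 (adjusted p = 1.05e-09), 2 were called over all genes and 5 higher and 0 lower when adjusted over the list alone. Among the 13 clock genes, 2 rose and 6 fell over all genes, 2 rose and 8 fell when adjusted over the list alone, and the median was -0.72 (adjusted p = 2.43e-07). These were the only 2 of the 49 lists whose calls held with an estimated correlation (adjusted p = 0.00213 for each). With a term for the 7 libraries that stood apart both passed with the preset correlation (eosinophil median 1.44, adjusted p = 0.000497; clock median -0.94, adjusted p = 9.23e-06). Neither then passed with an estimated one (adjusted p = 0.0677 for eosinophil and 0.0507 for clock genes). Between uninfected libraries 1 to 3 and 4 to 6 the eosinophil markers had a median difference of -0.29, with 1 of 6 members lower, and the clock genes one of -0.09, with 2 higher and 4 lower of 13. Mast cell and basophil markers moved toward higher values (7 of 9 members above 0, median 0.77, adjusted p = 4.07e-05), with 0 members called over all genes and 3 when adjusted over the list alone. Their members MS4A2, KIT and HDC, a receptor chain for IgE, the stem cell factor receptor and the histamine-forming enzyme, differed by 0.90, 0.92 and 1.04, and the call was lost with an estimated correlation (adjusted p = 0.251).

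The other 10 lists called in this contrast differed less, and none held with an estimated correlation. Type 2 cytokines and receptors had a median of 0.13 (adjusted p = 0.0168; 0.246 with an estimated correlation), with PTGDR2 (0.97) and CCR4 (0.71), receptors of type 2 lymphocytes, called when adjusted over the list alone. Genes induced by IL-4 and IL-13 had a median of 0.19 (adjusted p = 0.0436; 0.251 with an estimated correlation), and ALOX15 was the 1 member called. Cholesterol synthesis genes had a median of 0.21 (adjusted p = 0.00172; 0.344 with an estimated correlation). In the leukotriene and prostaglandin list the median was -0.00145 while the mean was 0.19 and the test pointed up (adjusted p = 0.0498; 0.252 with an estimated correlation). Toward lower values went oxidative phosphorylation genes (10 of 10 members below 0, median -0.40, adjusted p = 1.44e-05; 0.344 with an estimated correlation), ribosomal protein genes (17 of 17 below 0, median -0.25, adjusted p = 0.000974; 0.811 with an estimated correlation). Unfolded protein response genes did so too (median -0.25, adjusted p = 3.97e-05; 0.251 with an estimated correlation). Over 23 alternative settings with the preset correlation the median of the oxidative phosphorylation list lay between -0.686 and -0.186, with the call kept in each. Type I interferon-stimulated genes (16 of 17 below 0, median -0.25, adjusted p = 0.0436), heat shock genes (-0.23, adjusted p = 0.00209) and glucocorticoid-induced genes (-0.10, adjusted p = 0.00925) also pointed down, with adjusted p = 0.85, 0.251 and 0.344 with an estimated correlation. The call of the interferon list was lost without uninfected library 3, 5 or 6 (adjusted p = 0.658, 0.643 and 0.12) or infected library 2, 3 or 5 (adjusted p = 0.208, 0.122 and 0.198), and that of the ribosomal list without uninfected library 4 (adjusted p = 0.847).

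**Figure D2:**
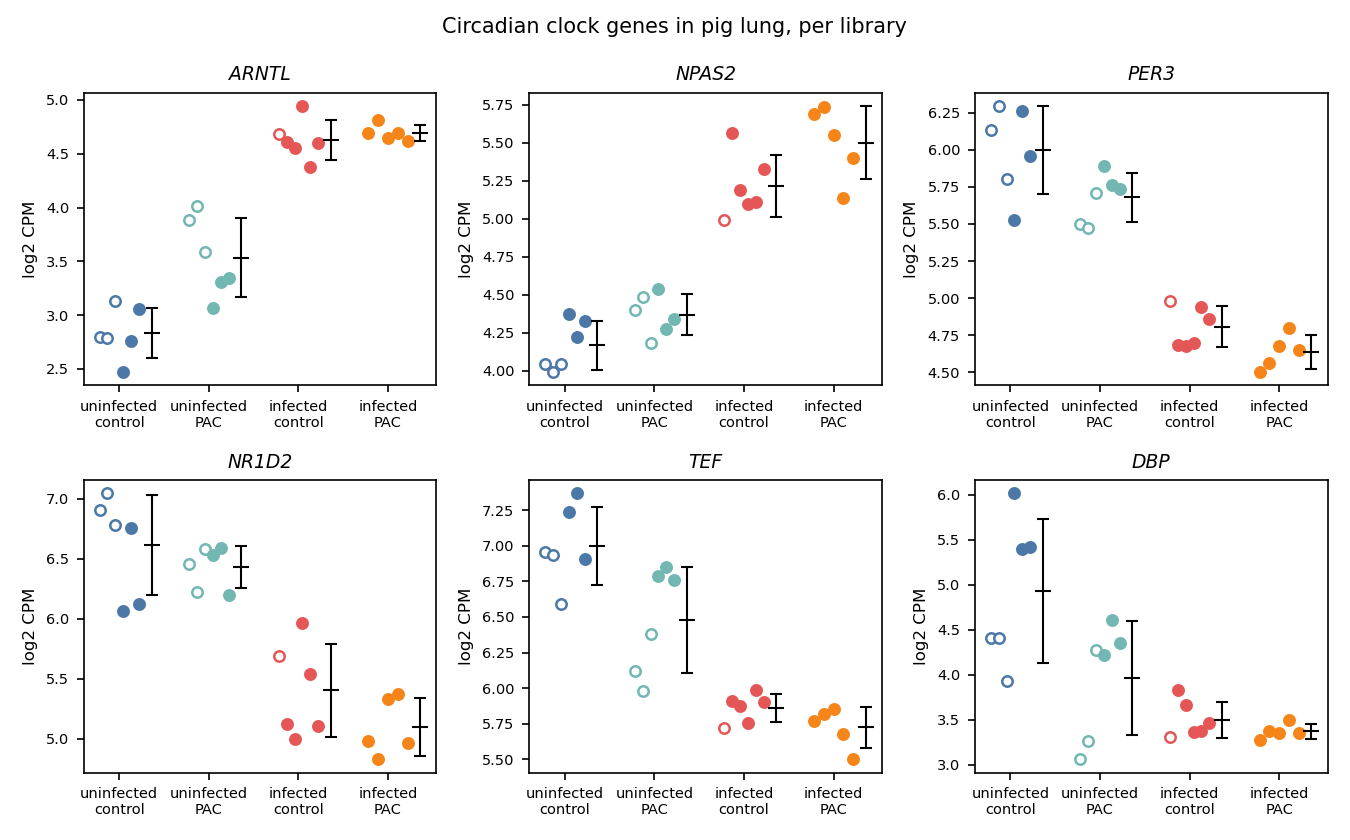
Log2 CPM (vertical axes) of the clock genes ARNTL, NPAS2, PER3, NR1D2, TEF and DBP in each of the 23 libraries, by group, with bars for the mean ± SD and open symbols for the 7 libraries that stand apart. All 6 infected libraries on the control diet lie beyond all 6 uninfected ones for each of the 6 genes.

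Under the PAC diet, infected pigs again had more CCR3 and CEBPE. Of the clock genes ARNTL and NPAS2 were again higher and NR1D2, PER3 and TEF lower, while DBP, NR1D1 and PER2 were not called. CCR3 lay at 3.19 ± 0.438 CPM in uninfected pigs (n = 6) and at 11.6 ± 7.24 in infected pigs (n = 5), and CEBPE at 0.534 and 4.53 CPM. LGALS13, a gene of the galectin family, lay at 3.35 and 65.9 CPM. ARNTL went from 11.8 ± 3.04 to 25.7 ± 1.39 CPM and PER3 from 51.4 ± 5.74 to 24.8 ± 1.99 CPM.

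This contrast asked which genes differed with infection when PAC was fed. The edgeR test called 14 genes, 11 higher and 3 lower, and 1501 genes had an unadjusted p under 0.05. DESeq2 called 52 and voom 167. LGALS13 rose by 4.31 (SE 0.80, adjusted p = 0.0407; 4 of 5 infected libraries above all 6 uninfected), and CEBPE by 3.07 (SE 0.53, adjusted p = 0.0221; 5 of 5). CCR3 rose by 1.86 (SE 0.35, adjusted p = 0.0407; 5 of 5) and MYBPC3, a gene of the heart muscle sarcomere, by 1.66 (SE 0.32, adjusted p = 0.0407; 3 of 5). RFLNB, CCR4, a chemokine receptor of type 2 lymphocytes, and KIF12 rose by 1.24, 1.14 and 1.03 (adjusted p = 0.0477 each; 5 of 5 each). NPAS2 rose by 1.15 (SE 0.12, adjusted p = 3.33e-05) and ARNTL from 11.8 to 25.7 CPM (adjusted p = 0.000883), each in 5 of 5 libraries. NR1D2 fell by 1.33 (SE 0.19, adjusted p = 0.0019), PER3 by 1.05 (SE 0.13, adjusted p = 0.000163) and TEF by 0.79 (SE 0.15, adjusted p = 0.0407), each in 5 of 5 libraries. The 2 further genes, LOC110259478 (2.44) and LOC110261245 (1.58), carry no symbol and were chosen after their values were seen. CEBPE (gene ID 100157564) spans 75926652 to 75929949 of chromosome 7 and LGALS13 spans 48205158 to 48209859 of chromosome 6. The count moved by more than 1.5 times whichever library was left out: it was 6, 6, 4, 5, 4 and 4 without uninfected PAC diet library 1 to 6 in turn and 7, 8, 4, 6 and 6 without infected PAC diet library 1 to 5. ARNTL, NPAS2, PER3 and NR1D2 kept their calls in all 11, while CEBPE lost its call in 7, CCR3, LGALS13, MYBPC3 and TEF in 9, RFLNB in 10 and CCR4 and KIF12 in 11 of the 11.

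In the PAC diet contrast 3 of the 6 uninfected libraries and 0 of the 5 infected ones belonged to the 7 that stood apart, and infected libraries 3 and 5 were among the 3 libraries highest in airway cartilage genes. A term for the 7 libraries left 7 genes called, 6 of the 14 among them, and leaving the 7 out left 6, 5 of the 14 among them. CCR3 then differed by 1.75 (adjusted p = 0.205) with the term and by 1.96 (adjusted p = 0.516) without the 7 libraries. Without the 3 libraries highest in cartilage genes 4 genes were called, and CCR3 differed by 1.03 (adjusted p = 0.859) and LGALS13 by 2.41 (adjusted p = 0.769). Among libraries numbered 1 to 3 CCR3 differed by 1.44 (adjusted p = 0.0939) and CEBPE by 2.97 (adjusted p = 0.051), and among those numbered 4 to 6 by 2.29 (adjusted p = 0.438) and 3.17 (adjusted p = 0.68).

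Camera with its preset correlation called 20 of the 49 lists under the PAC diet, 12 toward higher and 8 toward lower values. Tuft cell markers moved toward higher values (8 of 9 members above 0, median 0.51, adjusted p = 0.00113), with 0 members called over all genes and 1 when adjusted over the list alone, and theirs was the 1 call that held with an estimated correlation (adjusted p = 0.0485). With an estimated correlation it was lost once a term for the 7 libraries (median 0.42, adjusted p = 0.0558) or the cartilage score (0.45, adjusted p = 0.0948) was added. Among them SUCNR1, the succinate receptor of tuft cells, differed by 1.67, TRPM5 by 0.77 and DCLK1 by 0.51. Eosinophil markers had a median of 1.06 (adjusted p = 0.000316; 0.0748 with an estimated correlation), with 1 member called over all genes and 5 higher and 1 lower when adjusted over the list alone. Clock genes had a median of -0.49 (adjusted p = 0.00064; 0.0574 with an estimated correlation), with 2 higher and 3 lower over all genes and 2 higher and 6 lower when adjusted over the list alone. Genes induced by IL-4 and IL-13 had a median of 0.27 (adjusted p = 0.00156; 0.0669 with an estimated correlation), with 6 higher when adjusted over the list alone, among them the chemokines CCL17 (2.59), CCL26 (2.45) and CCL22 (1.43). Mast cell and basophil markers had a median of 0.44 (adjusted p = 0.0102; 0.488 with an estimated correlation). Interferon genes pointed down. All 14 members of the interferon gamma list (median -0.44, adjusted p = 1.39e-12; 0.0574 with an estimated correlation; 7 lower when adjusted over the list alone) lay below 0. So did all 17 of the type I list (median -0.57, adjusted p = 8.32e-11; 0.262 with an estimated correlation). CXCL10 and CXCL11, chemokines induced by interferon gamma, differed by -1.29 and -1.56, and CXCL10 lay at 66.0 ± 25.4 CPM in uninfected and 27.1 ± 16 in infected pigs. Between uninfected libraries 1 to 3 and 4 to 6 the interferon gamma list had a median difference of 0.10 and the type I list one of 0.04.

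Genes of the airway wall and of connective tissue pointed to higher values in infected pigs on the PAC diet, and the 2 infected libraries of this diet with the most cartilage transcripts, numbers 3 and 5, also had the most MUC5AC (210 and 569 CPM). The goblet cell and mucus list had all 11 members above 0 and a median of 3.11 (adjusted p = 5.37e-07; 0.314 with an estimated correlation), with 0 members called over all genes and 10 when adjusted over the list alone. Its members CLCA1 and FCGBP, secreted with mucus, differed by 6.0 and 5.61, and FCGBP spanned 16.6 to 2820 CPM in infected and 10.6 to 16.8 CPM in uninfected pigs. With the mean level of airway cartilage genes as a covariate the median of this list was 0.921 (adjusted p = 7.26e-07; 0.138 with an estimated correlation). In the control diet contrast the list had a median of 1.42 (adjusted p = 0.0629), and 0.614 (0.00275) with the cartilage covariate. With an estimated correlation neither passed (adjusted p = 0.85 and 0.433). Infected control diet library 2 lay far above the others of its group, with MUC5AC at 625 CPM against 1.23 to 6.83 CPM. Without it the difference between diets in the infection change of the list had a median of 4.09 in place of 1.5. The control diet median of 1.42 thus rests largely on that library. Ciliated cell genes (median 0.48, adjusted p = 0.0102), club cell genes (0.77, adjusted p = 0.0294) and smooth muscle markers (0.31, adjusted p = 0.00156) also pointed up, with adjusted p = 0.514, 0.514 and 0.435 with an estimated correlation. Extracellular matrix and fibrosis genes had 17 of 18 members above 0 (median 0.43, adjusted p = 1.26e-07; 0.1 with an estimated correlation), with 4 called when adjusted over the list alone, among them the collagen genes COL1A1 (1.28) and COL1A2 (0.90). Alveolar macrophage markers pointed down (median -0.34, adjusted p = 0.000114; 0.261 with an estimated correlation). The other 7 lists called were monocyte markers (-0.27), cytotoxic cell markers (-0.16), cell division genes (-0.14), unfolded protein response genes (-0.15), germinal centre genes (0.26), cardiac muscle genes (0.53) and cholesterol synthesis genes (0.10). Their adjusted p lay between 0.00819 and 0.0484, and between 0.262 and 0.514 with an estimated correlation. Without infected PAC diet library 3 the number of lists called was 13.

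**Figure D3:**
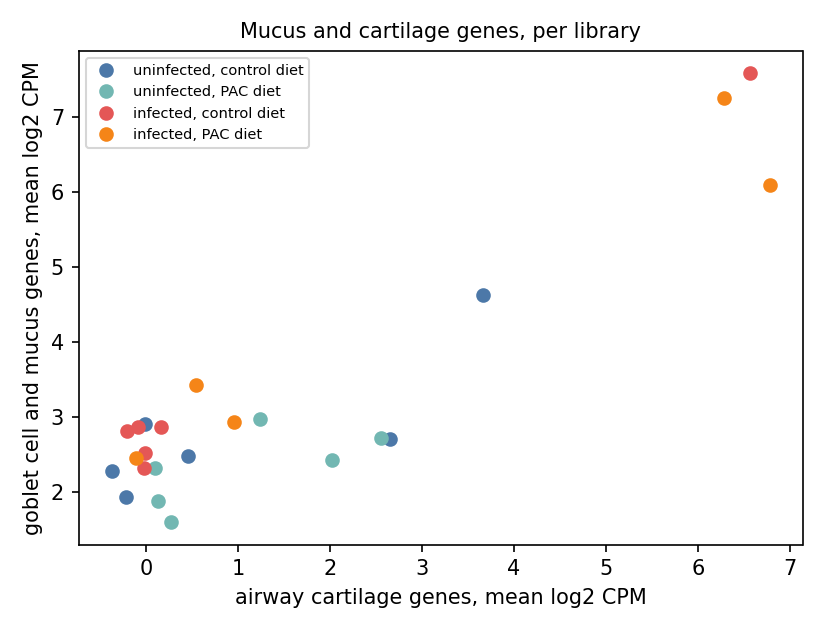
Mean log2 CPM of goblet cell and mucus genes (vertical axis) against mean log2 CPM of airway cartilage genes (horizontal axis), 1 point for each of the 23 libraries, coloured by group. Infected control diet library 2 and infected PAC diet libraries 3 and 5 lie at 6.57, 6.78 and 6.28 for airway cartilage genes and at 7.57, 6.09 and 7.25 for goblet cell and mucus genes, above the other 20 libraries on both axes.

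The infection contrast averaged over both diets called more genes, the one for eosinophil peroxidase among them. Its median SE was 0.139, against 0.192 under the control diet and 0.202 under PAC, so that smaller differences could pass. EPX, the granule peroxidase of eosinophils, lay at 0.479 and 0.503 CPM in uninfected and at 1.92 and 3.92 CPM in infected pigs on the control and PAC diets, and 4 of 6 and 4 of 5 infected libraries lay above all uninfected ones. SUCNR1 lay at 0.802 and 0.903 CPM in uninfected and at 3.14 and 2.90 CPM in infected pigs. BST2, an interferon-induced antiviral protein, was the only gene outside the clock among the 7 lower ones.

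The mean contrast called 50 genes by edgeR, 43 higher and 7 lower, with 2351 at an unadjusted p under 0.05. DESeq2 called 328, voom 3827 and edgeR with 1 surrogate variable 463, so that the number depends on the method. Among called genes with a symbol and a mean of at least 1 CPM the largest rises were those of LGALS13 (3.85, SE 0.56, adjusted p = 0.000929), CEBPE (2.96, SE 0.37, adjusted p = 9.55e-05), ST6GALNAC1 (2.73, SE 0.57, adjusted p = 0.0346), a sialyltransferase, and EPX (2.48, SE 0.49, adjusted p = 0.0199). CCR3 rose by 1.96 (SE 0.25, adjusted p = 0.000103) and OLIG1 by 1.94 (SE 0.30, adjusted p = 0.00161). CD1E, a gene of the CD1 family, rose from 3.68 to 9.10 CPM under the control diet. The others among the 10 were CLCA4 (1.84, SE 0.39, adjusted p = 0.0386), SUCNR1 (1.81, SE 0.33, adjusted p = 0.00848) and ALOX15 (1.81, SE 0.27, adjusted p = 0.000929). OLIG2 (3.77, adjusted p = 0.000564) falls outside that rule and was chosen after its values were seen. NR1D2 fell by 1.27, NR1D1 by 1.18, DBP by 1.15, PER3 by 1.13 (SE 0.09, adjusted p = 1.82e-08), TEF by 0.98, PER2 by 0.78 and BST2 by 0.62 (SE 0.13, adjusted p = 0.043). With a term for the 7 libraries that stood apart 383 genes were called, 44 of the 50 among them, and without those libraries 60 were, 19 of the 50 among them. No regroupings were run on these fits, so that the higher numbers need not be due to infection. Without uninfected control diet library 4 the count was 85, and EPX lost its call without uninfected control diet library 3 (adjusted p = 0.0503), uninfected PAC diet library 1 (0.0533) or infected PAC diet library 1 (0.0712). ST6GALNAC1, CLCA4, CD1E and BST2 lost theirs in 13, 15, 8 and 16 of the 23 left-out libraries, and the other 12 kept theirs in all 23. Within libraries numbered 1 to 3 and 4 to 6, CCR3 differed by 1.94 and 1.99 (adjusted p = 0.00817 and 0.0232), ARNTL by 1.27 and 1.63, and PER3 by -1.18 and -1.12. All uninfected libraries numbered 1 to 3 belong to the 7 that stood apart, so that infection is confounded with that structure in numbers 1 to 3.

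Genes named beforehand for worm infection were given in both infection contrasts whatever their result, and edgeR called none of those tested in either. The epithelial alarmin IL33 differed by -0.16 under the control diet and 0.19 under the PAC diet, and the type 2 cytokine IL13 by 0.70 and 0.47, from 3.05 and 4.03 CPM in uninfected to 4.97 and 5.58 CPM in infected pigs. IL10, an anti-inflammatory cytokine, differed by -0.49 and -0.56 (adjusted p = 0.45 and 0.475), from 9.96 and 10.0 to 7.07 and 6.82 CPM, with 3 of 6 and 5 of 5 infected libraries below all uninfected ones. FOXP3, the factor of regulatory T cells, differed by 0.16 and 0.41, GATA3, the factor of type 2 lymphocytes, by 0.28 and 0.24, and the eosinophil chemokine CCL26 by 1.01 and 2.45 (adjusted p = 0.563 and 0.218). EPX differed by 2.0 and 2.96 (adjusted p = 0.384 and 0.214) and the mucin MUC5AC by 3.84 and 5.73 (adjusted p = 0.476 and 0.404). Without infected control diet library 2 the MUC5AC difference under the control diet was -1.08. Under PAC DESeq2 called EPX, CCL26 and MUC5AC (adjusted p = 0.0103, 0.0159 and 0.0195), and with numbers 1 to 3 alone GATA3 and ARG1 were called (adjusted p = 0.0415 and 0.0422). In numbers 1 to 3 all uninfected libraries belong to the 7 that stood apart, so that infection is confounded with that structure there. Under the control diet voom called GATA3 (adjusted p = 0.0379). ARG1 differed by -0.22 and -0.29, CHIA by -0.82 and -0.31, POSTN by 0.01 and 0.10 and FCER1A by 0.57 and 0.83. IL4, IL5, CCL11 and CPA3 were below the filter on low counts: over all 23 libraries IL4 had 47 counts, IL5 152, CCL11 10 and CPA3 0, which allows a share of up to 0.00781 CPM of the raw total. In a fit without the filter, IL4 differed by 1.03 (SE 0.78) and 0.30 (SE 0.89), IL5 by -0.41 (SE 0.46) and -0.10 (SE 0.51) and CCL11 by 0.48 (SE 1.29) and 3.22 (SE 1.41). None of these was called (smallest adjusted p 0.62), and CPA3 was not tested.

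In uninfected pigs, PAC diet and control diet lungs showed no gene that passed the edgeR test. The shifts of gene groups were small, none held with an estimated correlation (adjusted p = 0.899 for each of the 7 called without it), and 50 of 100 regroupings of the libraries gave as many. Cell division genes pointed slightly higher with PAC: 22 of 24 members were above 0 with a median of 0.29, and MKI67, a marker of dividing cells, went from 96.4 ± 18.7 to 142 ± 36.8 CPM (n = 6 each). All 17 ribosomal protein genes lay lower, with a median of -0.38 that went to -0.10 without uninfected control diet library 4. ARNTL lay at 7.09 ± 1.16 CPM with the control diet and 11.8 ± 3.04 with PAC.

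This contrast asked what PAC did in the absence of worms. The edgeR test called 0 genes (smallest adjusted p 0.344), with 1668 at an unadjusted p under 0.05 and 883 by chance. Voom with sample weights called 0 genes and DESeq2 called 4. These 4 were chosen after their values were seen. AP5S1 (0.83, DESeq2 adjusted p = 0.0018; edgeR adjusted p = 0.344) spanned 5.75 to 10.1 CPM with the control diet and 12.2 to 15.7 CPM with PAC. ARNTL differed by 0.73 (DESeq2 adjusted p = 0.0109; edgeR 0.468). ZG16B was at 0 in all 6 PAC libraries and at up to 12.8 CPM with the control diet, and CBR1 reached at most 0.261 CPM. Camera with its preset correlation called 7 lists and 0 with an estimated correlation, with which each had an adjusted p of 0.899. Higher were cell division genes (adjusted p = 1.23e-07; 2 members called when adjusted over the list alone) and T cell markers (median 0.11, adjusted p = 0.0265). Lower were ribosomal protein genes (adjusted p = 4.21e-07; 0.00901 without uninfected control diet library 4), oxidative phosphorylation genes (-0.35, adjusted p = 0.000438; 0.0124 without uninfected control diet library 4), and heat shock genes (-0.26, adjusted p = 0.00251). So were smooth muscle markers (-0.42, adjusted p = 0.00502) and alveolar type 1 cell markers (-0.33, adjusted p = 0.0378). There were 4 lists called without uninfected PAC diet library 3 or 5. In this contrast 3 of 6 libraries of each diet belonged to the 7 that stood apart, and between uninfected libraries 1 to 3 and 4 to 6 smooth muscle markers differed by -0.52 with 5 of 10 lower. Cell division genes differed there by 0.12, with 2 higher and 6 lower of 24.

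In infected pigs, interferon genes pointed to lower and matrix genes to higher values with the PAC diet, without a gene that passed and without a list that held with an estimated correlation. All 17 type I interferon-stimulated genes lay below 0 (median -0.31) and the interferon gamma list had a median of -0.23, with CXCL10 at 44.5 ± 14.3 CPM under the control diet (n = 6) and 27.1 ± 16 under PAC (n = 5). Extracellular matrix genes had a median of 0.28, with the proteoglycan gene DCN at 0.57 and COL3A1 at 0.36. CCR3 lay at 13 and 11.6 CPM and ALOX15 at 14.8 ± 7.51 and 6.11 ± 2.91 CPM.

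The contrast asked whether PAC altered the infected lung. The edgeR test called 0 genes (smallest adjusted p 1), with 314 at an unadjusted p under 0.05 and 883 by chance. With fewer small p than by chance the test may be too strict, so that 0 calls do not show that PAC has no effect. Voom called 0 genes and DESeq2 2. These 2 were chosen after their values were seen. GFPT2, the first enzyme of the hexosamine pathway (1.84, DESeq2 adjusted p = 0.0162; edgeR 1), spanned 1.07 to 4.57 CPM with the control diet and 5.67 to 13.7 CPM with PAC. LOC102167067 was at 0 in all 6 control diet libraries and at up to 5.83 CPM with PAC. Camera with its preset correlation called 14 lists, 7 in each direction, and 0 with an estimated correlation. The smallest p were those of extracellular matrix (adjusted p = 5.92e-07; 0.322 with an estimated correlation), type I interferon (2.32e-06), interferon gamma (8.1e-06) and leukotriene and prostaglandin genes (median -0.15, adjusted p = 0.00226; 0.21 with an estimated correlation). The first 3 of these were called in each of 22 alternative settings with the preset correlation, and in none with the estimated one. The others were neutrophil (-0.10), alveolar macrophage (-0.17), platelet (-0.27) and heat shock (-0.08) lists toward lower values. Toward higher values were B cell (0.15), T cell (0.10), goblet cell (0.43), cell division (0.14), ciliated cell (0.31) and cardiac muscle (0.39) lists. In that order they were called in 8, 13, 9, 17, 6 and 5 of the 22 alternative settings. The goblet cell median lay between -0.838 and 3.28 there, and the ciliated cell median between -0.0347 and 0.618. Infected control diet library 2 and infected PAC diet libraries 3 and 5 were the highest in airway cartilage genes. Apart from the extracellular matrix and leukotriene lists the adjusted p with an estimated correlation lay between 0.697 and 0.83. The number of lists was 8 without infected control diet library 3 or 5 and 9 without infected control diet library 6 or infected PAC diet library 3.

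The 25 genes called for infection in either diet had the same sign in the other diet, where 18 of them were not called. Of the 18 genes called under the control diet 7 were also called under PAC: CCR3, CEBPE, ARNTL and NPAS2, higher in infected pigs of both diets, and NR1D2, PER3 and TEF, lower in both. Independent draws would share 0.00748 higher and 0.00102 lower genes. These numbers assume that the contrasts have no cause in common. Uninfected libraries of both diets were among the 7 libraries that stood apart, and infected and uninfected pigs might have been sampled at different hours. An overlap above these numbers thus need not be due to infection. All 18 genes called under the control diet and all 14 called under PAC had the same sign in the other diet. Infected pigs of both diets had ARNTL near 25 CPM (24.8 and 25.7), while uninfected pigs on PAC lay at 11.8 CPM against 7.09 CPM on the control diet.

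Whether PAC altered the response to infection was tested as the interaction of infection and diet. The edgeR test called 0 genes (smallest adjusted p 0.794), with 726 at an unadjusted p under 0.05 and 883 by chance, and DESeq2 and voom called 0 as well. For PAC averaged over infected and uninfected pigs edgeR, DESeq2 and voom also called 0 genes, with 686 at an unadjusted p under 0.05 by edgeR. The 726 and the 686 lie under the chance number, so that the 0 calls do not show an absence of effect. Over all genes tested the infection changes in the diets correlated across genes with r = 0.400 (Spearman's rho 0.174), and over the 50 genes called in the mean of the diets, which were chosen for their change, with r = 0.886. The value over all genes was reached by 17 of 100 regroupings of the libraries. Genes are not independent replicates. The 43 higher genes had medians of 1.06 under the control diet and 1.15 under PAC, and the 7 lower genes medians of -1.21 and -0.79. Fry of limma gave adjusted p = 0.912 for the interaction of the higher and adjusted p = 0.117 for that of the lower genes, over these 2 tests. Camera with its preset correlation called 8 lists for the interaction and 0 with an estimated correlation (adjusted p = 0.767 for each of the 8). The infection difference was higher under PAC for goblet cell and mucus genes (median difference 1.5, 11 of 11 members above 0, adjusted p = 0.033), extracellular matrix (0.46, adjusted p = 0.000326), smooth muscle (0.38) and ribosomal protein genes (0.36, adjusted p = 0.00137). The goblet median was 0.56 (adjusted p = 0.256) without uninfected control diet library 2, 4.09 without infected control diet library 2 and 0.23 (adjusted p = 0.409) without infected PAC diet library 5. Its call was also lost with the cartilage covariate (0.325, adjusted p = 0.349), where cartilage was high in 1 of 6 infected libraries on the control diet and 2 of 5 on PAC. The ribosomal median was 0.08 (adjusted p = 0.317) without uninfected control diet library 4. The infection difference was lower for interferon gamma (-0.31, adjusted p = 0.000124), type I interferon (-0.40, adjusted p = 0.00293), leukotriene and prostaglandin (-0.36) and cell division genes (-0.18). Without uninfected control diet library 2 the lists called were 4, and without library 6 of that group 14. Without uninfected PAC diet library 2 they were 13 and without library 6 of that group 5. Without infected control diet library 1, 3 or 4 they were 14, 4 and 4, and without infected PAC diet library 3 they were 5. Without the 7 libraries that stood apart 5 lists were called, and the goblet cell list then had an adjusted p of 0.482.

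The libraries themselves fell into sets that the groups do not describe. Among the 12 uninfected pigs, libraries numbered 1 to 3 differed from those numbered 4 to 6 in 6554 of 16810 genes (3099 higher and 3455 lower, edgeR, median absolute log2 fold change 0.557). Among the 11 infected pigs the same test called 0 genes, with 409 at an unadjusted p under 0.05. A score over 500 of these genes, chosen after the difference was seen, lay between 0.331 and 0.499 in the 6 uninfected libraries numbered 1 to 3 and between -0.579 and -0.173 in the other 6. It lay at 0.402 in infected control diet library 1 and between -0.274 and 0.107 in the other 10 infected libraries. Airway cartilage genes, a list written after the data were seen, were highest in infected control diet library 2 and infected PAC diet libraries 3 and 5.

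**Figure D4:**
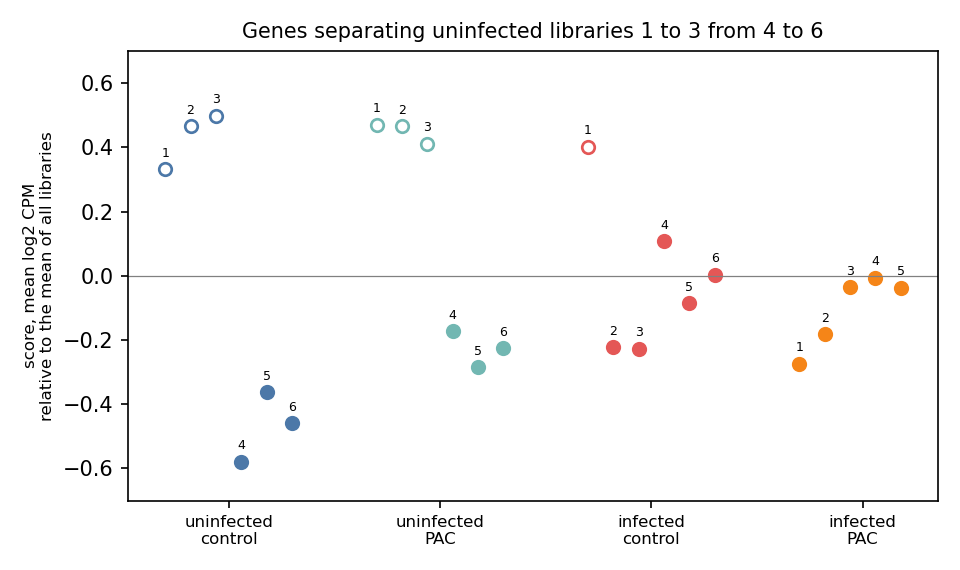
Score over 500 genes (mean log2 difference, vertical axis) in each of the 23 libraries, by group, with open symbols for the 7 libraries that stand apart. The 6 uninfected libraries numbered 1 to 3 lie between 0.331 and 0.499 and infected control diet library 1 at 0.402, and every other library at or under 0.107.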

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

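Among the tests in this part, those on handling in every group, on the leftmost libraries, on time of day for the clock genes with its 3 scores, on the clock genes without the 7 libraries, and both on airway wall were chosen after the result was seen, while the regroupings of libraries, the clock score as a covariate for the library structure and the eosinophil slope were chosen before their own values were seen. The clock score itself was built after the data were seen.

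Single libraries lay far from the others of their group for 11 of 156 sets of values (39 genes in 4 groups), where chance gives about 1 in 20, or 7.8. In uninfected pigs on the PAC diet CEBPE was at 0.0577 CPM in library 3 (others 0.402 to 0.807) and ALOX15 at 5.56 in library 5 (2.27 to 2.59). In infected pigs on the control diet PER2 was at 24.4 (38.1 to 47.2) and LGALS13 at 62.6 (25.1 to 32.9) in library 4, and ST6GALNAC1 at 42.1 (1.81 to 4.55) and MUC5AC at 625 (1.23 to 6.83) in library 2. In infected pigs on the PAC diet CCR4 was at 14.7 (10.9 to 11.6) and GATA3 at 41.1 (32.1 to 34.5) in library 1, and IL13 at 1.19 (5.43 to 7.69) in library 2. In uninfected pigs on the control diet SUCNR1 was at 0.323 (0.761 to 1.18) in library 4 and MUC5AC at 24.5 (2.12 to 5.24) in library 2.

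The infection change differed between diets for 8 lists by camera with the preset correlation, none of them with an estimated one (adjusted p = 0.767 each). The median differences, PAC diet minus control diet, were 1.5 for goblet cell and mucus genes, -0.365 for leukotriene and prostaglandin genes, -0.308 for interferon gamma genes, -0.404 for type I interferon genes, -0.179 for cell division genes, 0.455 for extracellular matrix genes, 0.382 for smooth muscle markers and 0.36 for ribosomal protein genes. Of 100 regroupings, 81 gave as many lists (8, highest other 26), so that chance is not excluded for this number.

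Regroupings of the same libraries show how often chance gives a count as large. For infection under the PAC diet 1 of 100, the real one, gave 14 genes or more (highest other 2), and for infection averaged over diets 1 of 100 gave 50 or more (highest other 3). Chance is unlikely for these counts, though 100 regroupings cannot give less than 1 in 100 and no adjustment was made over the counts. In the mean of diets 6 of the 7 libraries that stand apart were uninfected, which few regroupings matched, so that infection is not separated from that structure. Under the control diet 3 of 100 gave 18 or more, which makes chance less likely, but the highest others, 5595 and 2825 genes, point to a structure of the samples. Both placed all 4 libraries that stand apart in 1 group, but the other 5 of the 7 regroupings that did so gave 0, so that this grouping alone does not account for it. For the contrasts with 0 genes called all 100 gave as many, the highest others being 3848 for PAC in uninfected pigs, where 5 of the 6 libraries that stand apart lay together (at most 4 in the other 4 such regroupings), 160 for PAC in infected pigs, 1 for the interaction and 317 for PAC averaged over infection groups. The numbers of lists called are within chance: 38 of 100 regroupings gave as many as the 13 for infection under the control diet (highest other 20), 9 as many as the 20 under the PAC diet (21), 50 as many as the 7 for PAC in uninfected pigs (18) and 56 as many as the 14 in infected pigs (30). The correlation of the infection changes between diets over all genes, 0.400, was reached by 17 of 100 (highest other 0.588), so that chance is not excluded for it.

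The first pattern is that uninfected libraries numbered 1 to 3 stand apart from those numbered 4 to 6 in 6554 genes, a number that 1 of 100 regroupings reached (highest other 2335). Handling apart of numbers 1 to 3 in every group is argued against, since the score of these genes differed by -0.0829 in infected pigs (95% interval -0.387 to 0.222) against 0.788 in uninfected ones; this excludes a difference of the uninfected size only, and the bound was widened after the value was known, as the upper limit lies slightly above the one first set. Time of day as the whole cause was tested with the clock score as a covariate. With it 3404 genes were still called, 3161 of them shared with the 6554, which is above the bound set beforehand. This does not decide the question, since 1 linear score need not take up every gene that varies with the hour. That the libraries in the leftmost columns were handled apart cannot be told apart from other causes, as no label gives an order of handling. The 7 are the leftmost columns of the counts, and infected control diet library 1 scored 0.402 with the uninfected libraries 1 to 3. Of all pairs, infected control diet library 1 and uninfected PAC diet library 2 had the lowest chi-square per gene (12.2), which does not use the score. This set of 7 was chosen after the scores were seen, with infected control diet library 4 next at 0.107. The TMM factors of the 7 lay between 1.05 and 1.07 against 0.815 to 1.03 in the others. The changes rose with gene length across genes (rho 0.264), while in the middle class of 5 by length 654 genes were higher and 815 lower. In place of the 6554 genes, 4387 were called with the airway cartilage score as a covariate and 4992 with EIF1AY. A difference between litters or pens, not given in the labels, is untested.

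The second pattern is that clock genes differ between infected and uninfected pigs, with a clock score 2.69 higher in infected pigs on the control diet and 2.06 on the PAC diet, where the score was built from genes called for infection, so that these values restate that choice and no test of them is given. The libraries that stand apart are argued against as the cause, since 9 clock genes were called in the mean of the diets with all libraries and 9 without the 7. Clock transcripts brought by eosinophils are argued against, since within the 11 infected pigs, with both scores centred by diet, the slope of the clock score on the eosinophil score was -0.084 (r = -0.226, permutation p = 0.503; rho = -0.0909, permutation p = 0.797; r = 0.304 without the 2 farthest), and the upper 95% limit of the share of the infection difference that eosinophils account for was 9.36% (21.6% without infected PAC diet library 2, 29.5% without the 2 farthest). Time of day at sampling cannot be told apart from infection, as no sampling times were used here and infected and uninfected pigs might have been sampled at different hours. Uninfected pigs on PAC lay 0.973 above those on the control diet (exact permutation within numbers 1 to 3 and 4 to 6 p = 0.005, the smallest the 400 regroupings can give), 41.0% of the infection difference of 2.37, and since that score rests on called genes, a score over the 13 clock genes fixed beforehand (0.953, same test p = 0.005) and one over 5 genes called in both diets (0.791, same test p = 0.005) were set beside it, so that clock scores also differ between groups that do not differ in infection; an effect of infection itself stays open and untested, as that needs pigs sampled at the same recorded hours.

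The third pattern is that mucus and airway genes are very high in 3 infected libraries. More airway wall in those pieces of lung is a candidate explanation: with the airway cartilage score as a covariate the median infection change of the goblet cell and mucus list under the PAC diet went from 3.11 to 0.921, and cartilage itself differed by 1.84 between infected and uninfected pigs on PAC (exact permutation p = 0.292) and by 0.0428 on the control diet (exact permutation p = 0.935). That infection raises mucus genes apart from airway wall cannot be told apart from this, since the smaller adjusted p of the list with an estimated correlation and the covariate was 0.138, with 10 of 11 members above 0, and 3 libraries are few. With a preset correlation the list passed in that fit (adjusted p = 7.26e-07).

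A further pattern, the eosinophil genes against the libraries that stand apart, was looked at and gave no decision, and its tests are given as values only. With a term for the 7 libraries the eosinophil list under the control diet had a median of 1.44 against 1.5 without it (camera adjusted p = 0.000497; 0.0677 with an estimated correlation).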

How the results depend on the processing

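The alternatives on replicate numbers 1 to 3 and 4 to 6, airway cartilage, clock score and the 7 libraries that stand apart were chosen after seeing the data, all others before. For named genes with a call, 165 of 192 values with 1 library left out kept it under the control diet, 57 of 132 under PAC and 336 of 391 in the mean of diets. In the other settings apart from the clock score 197 of 240, 98 of 180 and 196 of 238 did. All others kept their direction and lost the call. With the clock score as covariate infection called 0 genes in either diet and in the mean. That score was built from genes called for infection, and its lowest value in infected libraries (0.171) lay above its highest in uninfected ones (-0.536). The covariate thus takes up the infection difference itself, and the lost calls do not show that the other genes follow the clock. Of the genes that the score is built from TEF, DBP and NR1D1 reversed, while ARNTL, NPAS2, PER3 and NR1D2 kept their direction. TEF was at 0.50 under the control diet, 0.50 under PAC and 0.50 in the mean, DBP at 1.15 (control diet) and 1.31 (mean), and NR1D1 at 1.16 and 1.15. NFIL3 was at -0.26 under the control diet and CLCA4 at -1.33 in the mean, whose cause was not tested. Genes called for infection under the control diet (18), under PAC (14) and in the mean (50) were 67, 52 and 328 by DESeq2 and 263, 167 and 3827 by voom with weights; DESeq2 called 4 and 2 for PAC in uninfected and infected pigs. With only the 2 groups compared they were 11 and 25, and with 1 surrogate variable 36, 9 and 463. In numbers 1 to 3 they were 9, 1476 and 4741, and in numbers 4 to 6 they were 3, 0 and 8, with fewer libraries. In numbers 1 to 3 all uninfected libraries belong to the 7, so that infection is confounded there. A term for the 7 libraries gave 232, 7 and 383, and leaving them out 193 and 6. Under PAC a replicate block gave 5, where same-number libraries had a mean r of 0.0345 over 33 pairs, EIF1AY as covariate 6, the cartilage covariate 4 and leaving out the 3 cartilage-rich libraries 4 (16 in the mean). Lists called with an estimated correlation were 2 and 1 for infection under the control diet and PAC and 0 for PAC in uninfected pigs, in infected pigs and for the interaction. With the preset correlation they were, with the clock score, 4 and 2 for infection and 6 for PAC in infected pigs, and without the 7 libraries 7 for infection under the control diet and 5 for the interaction, which had 14 with 1 surrogate variable. For PAC in infected pigs they were 8 without a filter, 6 with only the 2 groups, 6 with the replicate block, 6 with numbers 1 to 3 against 4 to 6 as a term, 6 with the cartilage covariate and 8 without the 3 libraries. Leaving out 1 library gave 12 to 22 genes under the control diet, 4 to 8 under PAC and 34 to 85 in the mean (85 without uninfected control diet library 4). It gave 10 to 17, 13 to 21, 4 to 10, 8 to 15 and 4 to 14 lists for infection under the control diet and PAC, PAC in uninfected and infected pigs, and the interaction. The correlation between diets was 0.886 over the called genes and 0.400 over all. Except where said, the cause of these differences was not tested. IL4, IL5 and CCL11 were tested only without the filter, and CPA3 was not.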

Other observations

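All tests in this part, exact permutation tests of scores, were chosen after the result was seen. The eosinophil score, the mean log2 CPM of the eosinophil markers, lay 1.23 higher in infected than in uninfected pigs on the control diet (exact permutation p = 0.00216, n = 6 against 6) and 0.873 higher on the PAC diet (exact permutation p = 0.0108, n = 5 against 6). These tests regroup libraries without regard to those that stand apart, of which 3 of 4 on the control diet and 3 of 3 on PAC were uninfected. Between uninfected libraries 1 to 3 and 4 to 6 the eosinophil markers had a median difference of -0.295. Between diets the eosinophil score differed by 0.192 in uninfected pigs (exact permutation p = 0.301) and by -0.167 in infected pigs (exact permutation p = 0.574). The clock score was 0.337 higher with PAC than with the control diet in infected pigs (exact permutation p = 0.013).

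Clock genes kept their direction within replicate numbers 1 to 3 and 4 to 6. Averaged over diets, NPAS2 differed by 1.24 in numbers 1 to 3 and 0.86 in numbers 4 to 6, NR1D2 by -1.52 and -1.04, TEF by -0.71 and -1.28, and DBP by -0.51 and -1.64. In numbers 1 to 3 infection is confounded with the libraries that stand apart. The first principal component held 25.5% and the second 14.4% of the variance. Their correlations with the airway cartilage score were 0.914 and -0.184, and with the Y-linked gene EIF1AY -0.359 and -0.804.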
